A study of Mus musculus with 2 samples.

How the data were processed

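Total RNA-seq was measured in liver of B6NCrl mouse embryos at embryonic day 11.5, a stage at which the fetal liver is a site of blood formation. The labels put both libraries in 1 group, as biological replicates 1 and 2. Replicate 1 was made from a pool of 109 embryos; replicate 2 was also a pool, whose number of embryos is not given in the sources used here. Both pools held male and female embryos. Per the labels' protocols, RNA was extracted with a mirVana kit, 10 ng of RNA went into each library, control RNAs were spiked in, and a protocol named for Smart-seq, a method for small RNA amounts, was followed.

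Each library came as a gene table and a transcript table. Per the labels, reads were assigned on mouse assembly mm10, and the text notes deposited with the tables name GENCODE release M4 and transcriptome alignments as the input of the quantification. The column names are those that the program RSEM writes, but the aligner, the quantifier and their versions are not given in the sources used here. The authors deposited estimated counts, which are reads shared out among genes by a model and need not be whole numbers. The deposited TPM values are relative to all features of a library, spike-ins included, so a larger spike-in share lowers the TPM of every gene. FPKM values, per the file headers, were deposited beside them. The deposited percent of each gene's expression carried by each transcript was used for isoforms. Per the file headers, each TPM also has a posterior mean and a credibility interval, whose level the header does not give.

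The tables held 69691 features: 43346 mouse genes, 97 spike-in sequences and 26248 short features with a number in place of a gene identifier and a median length of 73 bases. Symbols, gene classes, coordinates and GC content came from GENCODE release M21 on GRCm38, the same assembly as mm10, matched on the Ensembl identifier without its version. Of the 43346 genes, 42462 matched. The 884 that did not match held 0.211% of gene counts in replicate 1 and 0.206% in replicate 2. Because M21 is a later release than M4, some coordinates can differ from those the authors used.

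Estimated counts totalled 34344230 in replicate 1 and 31477397 in replicate 2, of which 31721267 and 29750192 lay on mouse genes. At this depth 3 counts, the limit that a count of 0 allows, correspond to a TPM of 0.0590 in replicate 1 and 0.0674 in replicate 2 for a gene of median effective length. Intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules.

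With 1 group and no control there was no test between conditions. The comparisons were the level of 32 gene lists, the globin composition, the order of 20 gene pairs, the agreement of the libraries, the differences between them and the main transcript of each gene. All were fixed before the data were examined, as were the lists and the alternatives, except where stated. Genes were named by a fixed rule. It took from each list the 4 genes with the highest mean TPM, genes of the pairs and members under a TPM of 1 in both libraries. It also took the 20 protein-coding genes with the highest TPM, and the 10 protein-coding genes most different between the libraries in each direction at a mean of 100 or more counts. For isoforms, it took list members at a TPM of 10 or more whose main transcript differed. Results of some genes that this rule selects are not reported here.

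A list's level was its median TPM per library, set against 10000 random lists of the same size drawn from 21474 protein-coding genes. A gene was called detected at a TPM of 1 or more in both libraries. Embryonic globin shares were computed from TPM after summing the near-identical adult copies. For pairs, the log2 ratio of TPM was taken with a pseudocount of 0.1. A pair was called ordered when both libraries gave the same order, the deposited credibility intervals did not overlap in either, and the mean log2 ratio exceeded the difference between the libraries. An exact sign-flip test of 2 values cannot go below p = 0.5, so no p-value is given for pairs.

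For differences between libraries, estimated counts were scaled with TMM factors from edgeR 4.0.16, in R 4.3.3, with spike-ins and numbered features left out. The pseudocount was 0.5 counts. Estimated counts were rounded to whole numbers for edgeR and DESeq2. The dispersion came from edgeR over genes at a CPM of 1 or more in both libraries. Genes at least 2-fold apart with a mean of 10 or more counts were counted beside 20 Poisson simulations of the same means. Each list's median log2 ratio was set against 10000 random lists of protein-coding genes matched on mean expression in 50 bins. These values describe the 2 libraries and test no condition. Intervals of a log2 ratio between libraries are 95% exact binomial intervals of the counts, and intervals of a share of counts are 95% Wilson intervals. Python 3.11.15, pandas 2.3.3 and scipy 1.17.1 did the other calculations.

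The steps were tested on simulated data. For replicate 1 against replicate 2, with dispersion 0.01, 200 genes with a mean of 100 or more counts were given a 4-fold change. All 200 came out past 2-fold in the right direction, and 194 of 16459 unchanged genes came out past 2-fold too. Recovery among genes with fewer counts, down to the minimum mean of 10 used for the reported numbers, was not tested. The list step, run on 16949 genes with 200 simulated lists of 12 genes, put 4% of unshifted lists outside the central 95% and found 98.5% of lists shifted by 0.5 on the log2 scale. This rate does not cover smaller shifts, such as those of most lists that lay outside the central 95% in the data.

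Alternatives were FPKM, posterior mean values, estimated counts, TPM over nuclear protein-coding genes, other thresholds, backgrounds and pseudocounts, DESeq2 1.42.0 size factors, and each replicate on its own. An adjustment of log2 ratios for GC content, length and expression was added after the data were seen. Of the 376 gene symbols in the lists, 4 had no match: Ahsp, Snhg1, Rn7sl1 and Zac1, the last an older name of Plagl1, which was in the same list. Apart from Plagl1, these were not analysed here.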

Results

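The series profiled total RNA from livers of mouse embryos at embryonic day 11.5, in 2 libraries from separate pools. Both libraries belong to 1 group, so levels within the tissue and differences between the pools could be described, but no condition could be tested. The libraries held 34344230 estimated counts in replicate 1 and 31477397 in replicate 2. Values are the mean ± SD over the 2 libraries (n = 2) unless a library is named, and coordinates are on GRCm38.

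Globin transcripts led the transcriptome. As estimated per gene, the 4 most abundant protein-coding genes were the alpha globins Hba-a2 (20203 ± 818 TPM) and Hba-a1 (9860 ± 349 TPM), the embryonic beta-like globin Hbb-y (11837 ± 487 TPM) and the adult beta globin Hbb-bt (7845 ± 786 TPM). The adult globins come in near-identical copies, so the levels and ranks of single copies are uncertain. Their sums were 30062 ± 1167 TPM for the alpha and 13535 ± 1605 TPM for the beta copies. The 7 globin genes of the lists together made up 6.08% of TPM in replicate 1 and 6.37% in replicate 2. Spike-ins held 14.6% and 11.1% of that TPM, so globin shares of mouse gene TPM alone were higher and closer to each other. Afp, the fetal counterpart of albumin (ENSMUSG00000054932.3, chromosome 5, 90490737 to 90508907), reached 5077 ± 537 TPM. The ferritin chains Ftl1 and Fth1, which store iron, stood at 4957 ± 198 and 3206 ± 176 TPM, and Gpx1, a peroxide-removing enzyme, at 2389 ± 122 TPM. The other members of the top 20 lay between 2875 TPM (Ldha and Rpl41) and 5690 TPM (Hbb-bs). They included the embryonic globins Hba-x and Hbb-bh1, the mitochondrial genes mt-Atp6 and mt-Atp8, the histone gene Hist1h2ap, the elongation factor Eef1a1, the chaperone Hspa8, the cyclophilin Ppia and the actin Actb. Hist1h2ap and Rpl41 share reads with near-identical copies, so their levels are uncertain. The level of mt-Atp8 is uncertain too, since this short gene overlaps mt-Atp6 and had only 10800 and 9933 counts in replicates 1 and 2.

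A TPM of 1 or more in both libraries was reached by 13464 of 43346 genes, among them 12165 of 21474 protein-coding genes. Protein-coding genes carried 76.6% of TPM in replicate 1 and 80.7% in replicate 2. These shares are of all TPM, of which spike-ins held 14.6% and 11.1% and all mouse genes 85.4% and 88.9%. Most of the gap between the libraries thus lies with the spike-ins. The 100 most abundant genes held 25.7% and 25.8% of all TPM in replicates 1 and 2. As shares of mouse gene TPM alone, both were higher, and the larger one was that of replicate 1.

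Embryonic and adult globins were present at the same time, in proportions that differed between the beta-like and the alpha-like genes. Embryonic Hbb-y and Hbb-bh1 made up 52.9% ± 3.88 of beta-like globin TPM, with 55.6% in replicate 1 and 50.2% in replicate 2. Embryonic Hba-x made up 10.4% ± 0.809 of alpha-like globin TPM, with 11.0% and 9.82%. Within the embryonic beta-like genes, Hbb-y (chromosome 7, 103851749 to 103853216) was 3.56-fold above Hbb-bh1 (3320 ± 75.6 TPM). On TPM, alpha-like transcripts exceeded beta-like ones by a factor of 1.17 ± 0.00766. Estimated counts, which do not correct for length, were nearly equal. They were 405158 alpha-like and 404311 beta-like in replicate 1, and 367590 and 371966 in replicate 2. As shares of estimated counts, the embryonic part of beta-like globin was 54.8% (Wilson interval 54.65 to 54.96%) in replicate 1 and 49.3% (49.1 to 49.5%) in replicate 2. The difference between the pools therefore exceeded counting error. The adult copies Hba-a1 and Hba-a2 are nearly identical, as are Hbb-bs and Hbb-bt, so the shares rest on their sums and the split between copies is uncertain.

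**Figure D1:**
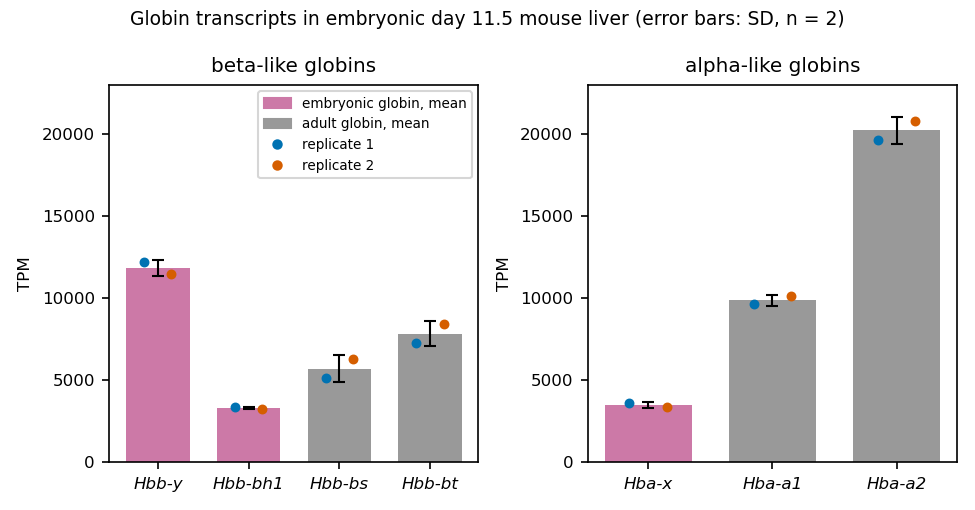
TPM of the 4 beta-like and 3 alpha-like globin genes (bars, mean; error bars, SD; points, the 2 replicates). The embryonic genes Hbb-y and Hbb-bh1 made up 52.9% of beta-like and Hba-x 10.4% of alpha-like globin TPM; the split between adult copies is uncertain.

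Red cell genes as a class stood among the most abundant of the tissue. The 15 erythroid regulators were all detected, with a median of 58.8 ± 4.40 TPM. They were led by Klf1 (377 ± 39.6 TPM; chromosome 8, 84901928 to 84905291), the activator of adult beta globin, by Lmo2 (147 ± 2.09 TPM) and Gata1 (125 ± 7.45 TPM), which act in the same DNA-binding complexes, and by Gfi1b (115 ± 9.07 TPM), a repressor needed for red cell formation. The 14 matched genes of the red cell membrane and surface had a median of 103 ± 5.64 TPM, including the blood group gene Ermap (206 ± 0.679 TPM), the transferrin receptor Tfrc (183 ± 20.6 TPM) and Rhd (176 ± 18.9 TPM). All 12 genes of haem synthesis and iron import were detected at a median of 129 ± 16.4 TPM. Among the highest were Alad (376 ± 25.6 TPM), Urod (272 ± 13.7 TPM) and Cpox (272 ± 17.5 TPM), all enzymes of the haem pathway. The list named for red cell autophagy and enucleation held 11 genes, all detected, with a median of 51.3 ± 6.14 TPM. It also includes other red cell genes. Among these were its highest members, the antioxidant Prdx2 (1090 ± 36.1 TPM) and the carbonic anhydrase Car2 (1053 ± 104 TPM). The level of this list is therefore not that of autophagy and enucleation genes alone. Each of these 4 lists lay above the 95th percentile of random lists of equal size in both libraries.

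Hepatoblast products were likewise abundant, but enzymes of the mature hepatocyte were mostly not detected. All 20 hepatoblast genes were detected, with a median of 181 ± 10.7 TPM. After Afp, the highest were transferrin, Trf (2066 ± 230 TPM), and the apolipoproteins Apoa2 (1771 ± 15.9 TPM) and Apoe (1123 ± 29.7 TPM). Alb, which encodes albumin, stood at 609 ± 31.4 TPM. Of the 18 genes of mature hepatocyte metabolism, 7 were detected and the list median was 0.158 ± 0.0247 TPM. The detected ones included glutamine synthetase, Glul (106 ± 5.19 TPM), and the urea cycle enzymes Ass1 (53.9 ± 6.04 TPM) and Otc (10.3 ± 0.679 TPM). The other 11 stayed under a TPM of 1 in both libraries. Among them Tdo2 (0.430 ± 0.198 TPM), Pck1 (0.160 ± 0.0283 TPM), Tat, Cyp2e1, Cps1, Cyp7a1 and Ugt2b1 had some counts. Cyp3a11, Cyp1a2, G6pc and Mup3 had 0 counts in both, which allows for G6pc, the last enzyme of glucose release, up to 0.0502 TPM in replicate 1 and 0.0575 TPM in replicate 2.

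Liver transcription factors were present at modest levels, with a list median of 6.48 ± 0.463 TPM and 15 of 16 members detected. Hhex (36.4 ± 2.08 TPM) and Gata4 (36.4 ± 2.63 TPM), both needed for early liver growth, were the highest, followed by Foxa3 (24.4 ± 2.16 TPM) and Tbx3 (16.3 ± 0.262 TPM). Markers of bile duct cells had a median of 7.81 ± 0.0495 TPM, with Prom1 (12.7 ± 0.205 TPM) and the keratin Krt7 (10.5 ± 0.707 TPM) on top, while the chloride channel Cftr was under a TPM of 1 in both libraries. These 2 lists lay between percentiles 74.5 and 76.3 of random lists.

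Blood lineages other than the red cell differed widely in level. Megakaryocyte genes had a median of 24.7 ± 0.286 TPM, above the 95th percentile, with the platelet chemokines Pf4 (686 ± 17.2 TPM) and Ppbp (121 ± 3.72 TPM), the integrin Itga2b (61.9 ± 0.233 TPM) and the adhesion receptor subunit Gp1bb (36.4 ± 4.13 TPM), although Selp was under a TPM of 1. Stem and progenitor genes had a median of 7.11 ± 0.0212 TPM, led by the stem cell factor receptor Kit (41.4 ± 7.62 TPM), Meis1 (36.0 ± 2.40 TPM), Myb (30.9 ± 2.998 TPM) and Cd34 (28.6 ± 1.79 TPM). Macrophage genes had a median of 13.3 ± 0.460 TPM, with lysozyme, Lyz2 (73.1 ± 6.48 TPM), the complement genes C1qb (62.3 ± 0.368 TPM) and C1qc (32.3 ± 0.318 TPM) and the adhesion molecule Vcam1 (50.7 ± 0.721 TPM). The granulocyte and mast cell list had a median of 3.24 ± 0.198 TPM but spanned a wide range, from the granule enzyme Mpo (156 ± 14.9 TPM), S100a8 (143 ± 6.68 TPM), S100a9 (73.8 ± 1.75 TPM) and Prtn3 (40.6 ± 0.651 TPM) down to Ctsg, Ms4a2, Mcpt8 and Cma1, all under a TPM of 1. Lymphoid genes had a median of 0.0750 ± 0.0212 TPM and only 2 of 12 were detected, Cd79b (4.82 ± 0.417 TPM) and Lck (4.51 ± 0.467 TPM). Rag1, Il7r, Cd79a, Vpreb1, Cd3g and Cd4 had few counts, and Cd3e, Pax5 and Igll1 had 0 counts in both libraries.

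Vascular and connective tissue markers were present at intermediate levels. Endothelial genes had a median of 13.9 ± 0.923 TPM, led by Egfl7 (134 ± 6.24 TPM), Oit3 (34.9 ± 2.67 TPM), the scavenger receptor Stab1 (27.1 ± 7.18 TPM) and the VEGF receptor Kdr (23.2 ± 2.64 TPM). Stellate and mesenchymal genes had a median of 23.1 ± 1.58 TPM, above the 95th percentile, with the collagens Col3a1 (239 ± 2.56 TPM), Col1a1 (161 ± 10.9 TPM) and Col1a2 (118 ± 2.63 TPM) and the matrix protein lumican, Lum (61.4 ± 3.005 TPM). Lrat, which esterifies retinol for storage, was under a TPM of 1 (0.165 ± 0.00707 TPM). Mesothelial genes had a median of 6.59 ± 0.442 TPM, with Podxl (22.3 ± 0.141 TPM), Upk3b (18.7 ± 0.290 TPM) and Wt1 (16.0 ± 0.375 TPM), and Msln under a TPM of 1.

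Proliferation genes were high. All 20 cell division genes exceeded a TPM of 10 in both libraries and their median was 228 ± 25.1 TPM. The highest were the mitotic kinase Cdk1 (356 ± 31.2 TPM), the nucleotide-producing Rrm2 (352 ± 42.6 TPM), the survival protein Birc5 (341 ± 7.76 TPM) and the replication clamp Pcna (327 ± 14.7 TPM). Fetal growth genes had a median of 41.7 ± 1.39 TPM, led by Hmga1 (537 ± 15.3 TPM), Myc (184 ± 10.4 TPM), Igf2bp2 (59.7 ± 1.16 TPM) and Igf2bp3 (43.8 ± 4.29 TPM). Imprinted genes had a median of 128 ± 5.46 TPM, led by Mest (652 ± 40.6 TPM), Dlk1 (601 ± 35.2 TPM), the non-coding H19 (390 ± 76.4 TPM) and the growth inhibitor Cdkn1c (356 ± 6.37 TPM). The hypoxia and glycolysis list had a median of 63.7 ± 4.30 TPM, with Ldha (2875 ± 267 TPM), Pgk1 (444 ± 51.6 TPM), Pfkl (180 ± 14.7 TPM) and Bnip3 (164 ± 15.8 TPM). All 4 lists lay above the 95th percentile in both libraries.

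Among signals that act on blood cells, Dlk1, the growth factor Igf2 (337 ± 36.5 TPM), fibronectin, Fn1 (135 ± 1.85 TPM), and the chemokine Cxcl12 (53.4 ± 3.79 TPM) were the highest, against a list median of 9.22 ± 0.898 TPM. Ccl21a, Fgf1 and Il6 were under a TPM of 1. Hamp, the iron hormone hepcidin, had 0 counts in both libraries, which allows up to 0.397 TPM in replicate 1 and 0.454 TPM in replicate 2. Immediate-early and heat-shock genes had a median of 9.24 ± 1.86 TPM, led by Dnajb1 (79.8 ± 4.10 TPM) and Ier2 (37.9 ± 3.44 TPM), with Fosb and Hspa1b under a TPM of 1. Reference genes had a median of 1260 ± 70.6 TPM, and abundant non-coding RNAs one of 61.9 ± 21.04 TPM, with Malat1 at 1834 ± 478 TPM, Gas5 at 600.4 ± 20.8 TPM and the telomerase RNA Terc under a TPM of 1. Sex-linked genes, measured in mixed-sex pools, had a median of 13.1 ± 1.51 TPM.

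Markers of organs outside the liver were mostly near or under the detection level, apart from heart muscle. Kidney and gonad genes had a median of 0.318 ± 0.0530 TPM, and 1 of 8 was detected, Sall1 (1.99 ± 0.177 TPM). Gut, pancreas and lung genes had a median of 0.305 ± 0.120 TPM, and 1 of 11 was detected, Barx1, a stomach mesenchyme factor (17.1 ± 1.28 TPM). Neural genes had a median of 1.010 ± 0.0566 TPM, with Gap43 at 16.3 ± 1.15 TPM and 5 of 11 under a TPM of 1. Skeletal muscle genes had a median of 1.70 ± 0.00707 TPM, with Tnnt1 at 20.7 ± 0.643 TPM and Myh3, Myf6 and Pax7 under a TPM of 1. Heart muscle genes had a median of 21.1 TPM in replicate 1 and 7.61 TPM in replicate 2. Altogether 15 of the 32 lists had a median above the 95th percentile of random lists in both libraries, and 6 had one below the 50th, or 13 against random lists of genes at a TPM of 0.1 or more.

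**Figure D2:**
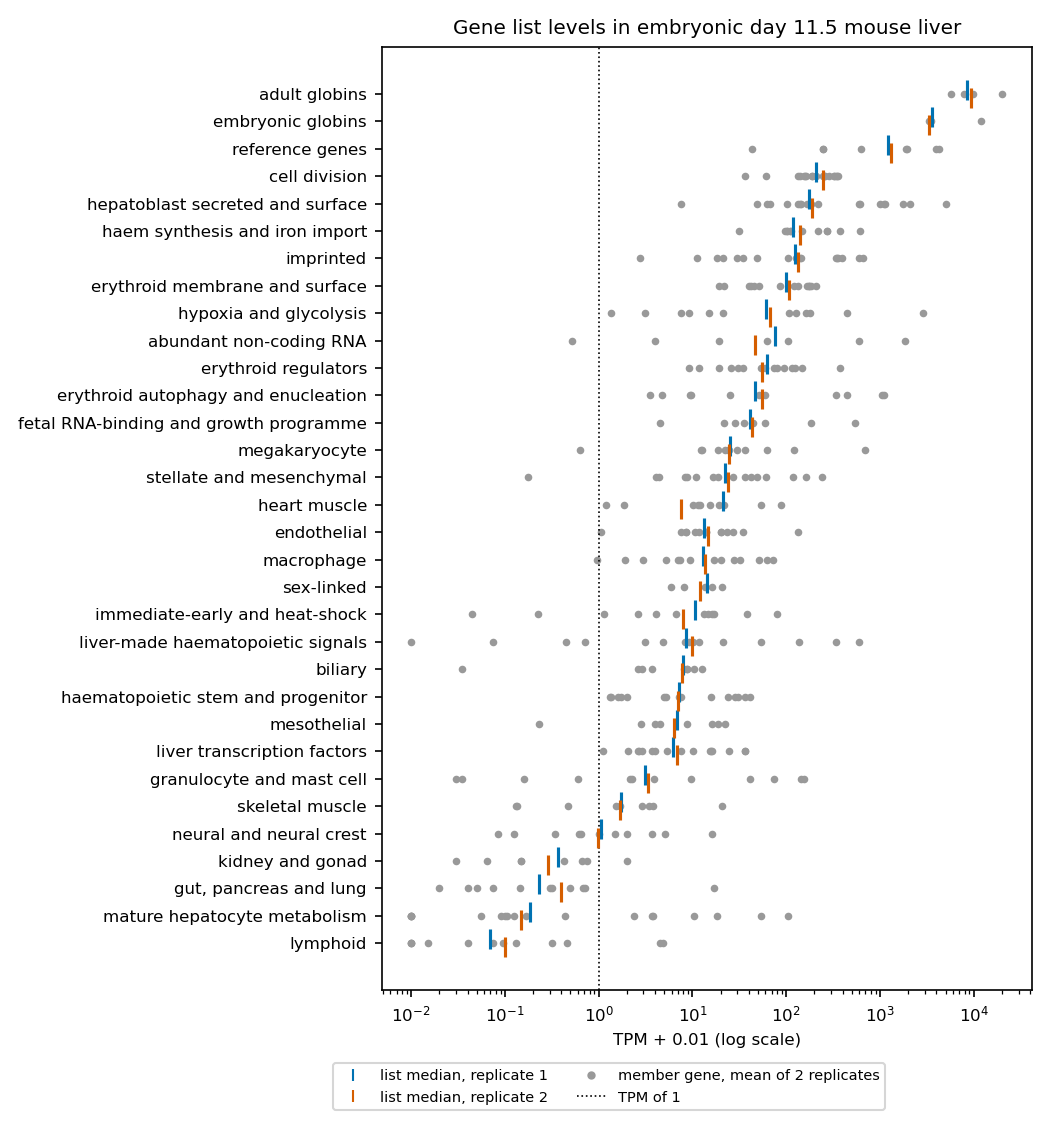
Levels of the 32 gene lists in TPM plus 0.01, on a logarithmic axis (grey points, member genes as means of 2 replicates; coloured ticks, list median of each replicate; dotted line, TPM of 1). Globin and reference gene lists stand at the top, followed by cell division, hepatoblast and haem lists, with lymphoid and mature hepatocyte lists at the bottom, and heart muscle has the widest gap between the replicates (21.1 and 7.61 TPM).

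Of 20 gene pairs fixed in advance, 18 were ordered alike in both libraries with a gap beyond the difference between them. The fetal protein Afp exceeded Alb 8.32-fold (log2 ratio 3.06 ± 0.08). Gata1 exceeded the progenitor factor Gata2 16.3-fold (4.02 ± 0.02). The erythroid enzyme Alas2 exceeded the housekeeping form Alas1 4.65-fold. Among liver factors, Foxa3 exceeded Foxa1 8.71-fold, while Cebpb exceeded Cebpa 2.05-fold. Krt18 exceeded Krt19 10.3-fold, and Lin28b, a fetal RNA-binding protein, exceeded Lin28a 4.67-fold. Smaller gaps separated Ccnb1 from Ccne1 (1.83-fold), Dlk1 from Meg3 (1.75-fold), Slc4a1 from Slc2a1 (1.30-fold), H19 from Igf2 (1.15-fold) and Igf2bp2 from Igf2bp1 (1.40-fold). The last of these was reversed when estimated counts replaced TPM (log2 ratio of Igf2bp1 over Igf2bp2 0.75 against -0.48). Hbb-y over Hbb-bh1 was ordered, and the 2 pairs of near-identical adult globin copies were too, but their split is uncertain. The pairs of Thpo and Epo (log2 ratio -0.56 ± 0.52) and of Stab2 and Lyve1 (-0.02 ± 0.11) did not exceed the difference between the libraries.

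The pools agreed closely across the transcriptome. Pearson's r of log2(TPM + 1) was 0.995 and Spearman's rho 0.946 across 43346 genes, which are not independent replicates. The biological coefficient of variation, as edgeR names it, was 7.88% over 13889 genes. It measures the spread between the 2 pools and their preparations, not between single embryos. The libraries were not the same reads deposited again, since a chi-square test over 16020 genes gave 10.4 per degree of freedom; separate preparation of 1 RNA sample would also exceed counting noise, so the test does not show separate material. Among 11522 protein-coding genes with a mean of 100 or more counts, the log2 ratio of replicate 1 to replicate 2 had an SD of 0.20. Still, 483 genes were at least 2-fold higher in replicate 1 and 243 in replicate 2, of 16607 with a mean of 10 or more counts, against means of 67.9 and 60.2 under Poisson sampling alone. On TPM in place of scaled counts the numbers were 290 and 206, and at a mean of 100 or more counts 28 and 4.

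Heart muscle genes stood apart between the pools. All 10 heart muscle genes were higher in replicate 1, with a median log2 ratio of 1.20 (2.30-fold), beyond the central 95% of random lists matched on expression (-0.14 to 0.11). Myl7, the atrial myosin light chain (chromosome 11, 5896637 to 5898782), was at 119 TPM in replicate 1 and 58.9 TPM in replicate 2, and the cardiac actin Actc1 (chromosome 2, 114047282 to 114053548) at 73.5 and 33.0 TPM. Of the 10 protein-coding genes most elevated in replicate 1, 9 encode a heart hormone or parts or regulators of striated muscle. This grouping was made after the values were seen. From the heart muscle list came Nppa (log2 ratio 2.19, interval 1.89 to 2.52), Myh6 (1.80), Myh7 (1.73) and Tnnt2 (1.53). Actn2 (1.59) is on the skeletal muscle list. Mybpc3 (1.99), Csrp3 (1.51), Ttn (1.43) and Ankrd1 (1.40) are on no list fixed in advance. The remaining gene of the 10, Gm14288 (4.91), and Gm14440, the gene most elevated in replicate 2 (-3.61), lie near each other on chromosome 2 among similar sequences, so both ratios are uncertain. On TPM, Gm14288 differed far less, at 3.74 in replicate 1 and 1.75 in replicate 2. The other 9 genes most elevated in replicate 2 were mt-Nd4l (-1.07) and, between -0.93 and -0.81, Card6, Astn1, Frzb, Slitrk6, Fam81a, B3gnt2, Serpinb6b and Nanp, which form no list fixed in advance. The place of Card6 and Nanp among them rests on scaled counts, since their TPM differed less (0.94 and 1.16 for Card6, 6.62 and 8.76 for Nanp in replicates 1 and 2).

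Of the 32 lists, 7 lay outside the central 95% between the pools, where 1.6 would by chance if members of a list varied independently. Members of 1 list can move together, so more than 1.6 can lie outside by chance. Besides heart muscle, abundant non-coding RNAs (median log2 ratio 0.43; Malat1 0.62, interval 0.59 to 0.65), immediate-early and heat-shock genes (0.25) and embryonic globins (0.17) had higher medians in replicate 1. The random lists held protein-coding genes only, so the range for the non-coding RNAs leaves out any shift of non-coding classes. Of the immediate-early and heat-shock genes, 8 of 12 were above 0, but not the 4 most abundant: Dnajb1 (-0.02), Ier2 (-0.10), Junb (-0.13) and Dusp1 (-0.26, interval -0.41 to -0.11). Sex-linked genes (-0.29), cell division genes (-0.15, with 17 of 20 members lower in replicate 1) and red cell membrane genes (-0.13) were higher in replicate 2. Among sex-linked genes, Xist, the RNA that silences an X chromosome in females, was higher in replicate 1 (0.44, interval 0.39 to 0.50), as was the median of long intergenic non-coding RNAs (0.18), and the Y-linked Ddx3y (-0.30), Eif2s3y (-0.29) and Uty (-0.31) were higher in replicate 2. The remaining Y-linked gene, Kdm5d, did not differ beyond counting error (-0.07, interval -0.24 to 0.10). The direction of these 7 lists held under each scaling tried. After adjustment for GC content, length and expression, chosen after the data were seen, embryonic globins (0.04) and red cell membrane genes (-0.05) moved inside the central 95%, and adult globins (-0.20), haem synthesis (-0.10), hepatoblast (-0.08) and imprinted genes (0.06) moved outside. The imprinted list holds non-coding genes too, so the limit of protein-coding random lists also applies to it.

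**Figure D3:**
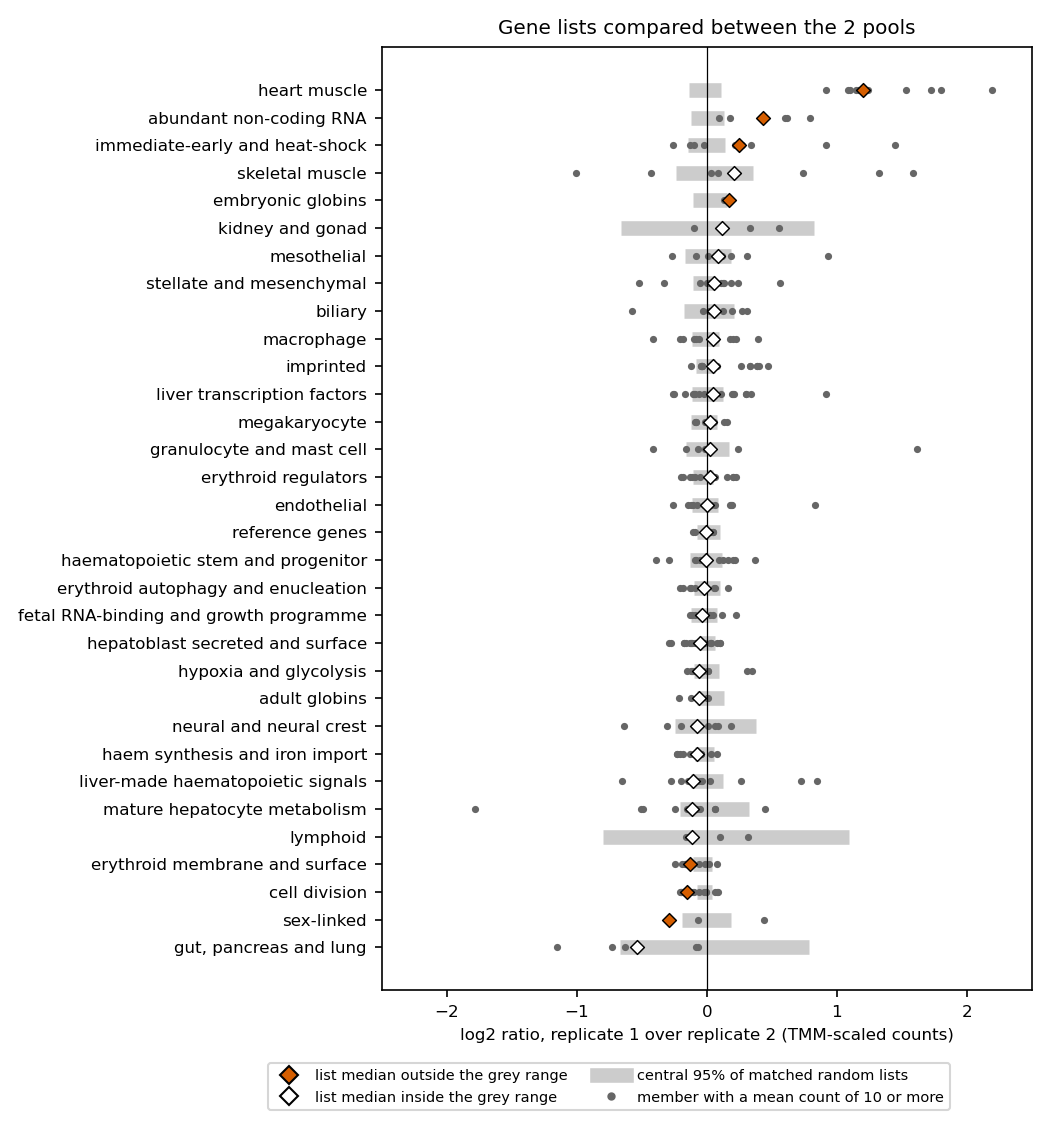
Log2 ratio of replicate 1 to replicate 2 for the 32 gene lists (diamonds, list median; grey bars, central 95% of 10000 random lists of protein-coding genes matched on expression; points, members with a mean of 10 or more counts). Heart muscle lies at 1.20, far beyond its grey bar, and 6 other lists lie outside by smaller amounts.

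Transcript estimates gave mostly the same main transcript in both pools. Of 9290 genes with 2 or more annotated transcripts and a TPM of 1 or more, 8408 (90.5%) had the same most abundant transcript. Among 159 list members at a TPM of 10 or more, 9 differed, among them Alas1, Ank1, Kit, Mirg, Postn, Reln, Stab2 and Tnnt1. In Kit, for example, the leading transcript of replicate 1 held 52.4% of the gene there and 43.1% in replicate 2.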

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

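The tests of skeletal muscle, of the share of male embryos, of Xist among non-coding RNAs and of the Y-linked genes alone were chosen after those values were seen, as was the adjustment for GC content, length and expression. The design has 1 group and names no biological difference to test, so the tests concern what the pools held and technical trends.

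Spike-in sequences, which no comparison used, took 7.64% of counts in replicate 1 (Wilson interval 7.63 to 7.65%) and 5.49% in replicate 2 (5.48 to 5.49%), far above the limit of 3 counts. Relative to scaled genes, the spike-ins were higher in replicate 1 by a median of 0.50 on the log2 scale, over 48 spike-ins with 100 or more counts. Their spread around that shift was an SD of 0.13, against 0.20 for protein-coding genes at the same minimum. The numbered short features held 43 counts in replicate 1 and 30 in replicate 2, also above the limit of 3.

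Heart muscle genes were higher in replicate 1, by a median log2 ratio of 1.20. The adjustment left 1.14, which argues against GC content and length as the whole cause. An additional list of 20 heart genes, fixed before their values were seen, had a median of 0.70, with 18 of 20 above 0. This is consistent with more heart tissue in the pool of replicate 1, as a hypothesis; Myl7, at 119 and 58.9 TPM, was the most abundant such gene. The 9 skeletal muscle genes fixed in advance had a median of 0.21 and went both ways, from -1.002 (Myh3) to 1.32 (Acta1) and 1.59 (Actn2), so a part played by skeletal muscle stays open.

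Y-linked genes were lower and Xist higher in replicate 1. The 4 Y-linked genes pooled gave a log2 ratio of -0.26 (interval -0.33 to -0.20), although Kdm5d alone did not differ beyond counting error, and their median of -0.29 lay at percentile 0.09 of 10000 random draws of protein-coding genes, which argues against ordinary scatter. Xist had a ratio of 0.44 (0.39 to 0.50) and lay at percentile 79.6 of 142 other long intergenic non-coding RNAs. As a class, these RNAs were higher in replicate 1. They were not matched to Xist on level, so their spread, -0.41 to 0.94, can include counting noise of genes with fewer counts. The rank therefore cannot decide whether the class shift accounts for Xist, and Xist is not used as separate evidence on sex. The gap between Xist and the Y-linked median, 0.74, was at percentile 100 of random draws, which used protein-coding genes also for Xist and so leave out that class shift. It was 0.63 after the adjustment, which argues against GC content and length as the whole cause. A lower share of male embryos in the pool of replicate 1 may account for the Y-linked part, though the labels give no numbers of male and female embryos.

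Smaller shifts of globins and of 4 lists were weighed against the same trend. The embryonic minus adult difference of beta-like globins was 0.32 before and 0.33 after the adjustment. The 4 genes are alike in GC content (46.8 to 51.3%) and were adjusted by similar amounts, so the fitted trend accounts for little of the difference. Before the adjustment it lay at percentile 99.1 of random draws, which argues against ordinary scatter of genes that vary independently. Genes that move together were not covered by those draws. The red cell membrane list went from -0.13 to -0.055, inside the range of random lists, so the trend could account for it. Cell division (-0.15 to -0.082), abundant non-coding RNA (0.43 to 0.26) and immediate-early genes (0.25 to 0.17) kept part of their shift, and what the trend contributes cannot be told apart from the remainder. For the non-coding RNA list, random lists of protein-coding genes also leave out any shift of non-coding classes.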

How the results depend on the processing

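With 2 libraries, leaving one out moves a mean by no more than its SD by construction, so it says nothing on stability; it cannot be done for agreement, dispersion or differences between libraries. Of 1412 alternative values, 1068 stayed within the spread used for them, 343 moved (212 of them levels in FPKM or in TPM over nuclear protein-coding genes, other units by construction) and 1 was reversed: Igf2bp1 over Igf2bp2, at a log2 ratio of 0.75 on estimated counts, which do not correct for length. The 1068 include many values that could not move. With each replicate left out, these were 229 gene levels, 32 list levels and 20 gene pairs. Another 32 were list levels under another background, which leaves a list median as it was. The 1068 therefore overstate stability. The adjustment for GC content, length and expression was chosen after the data were seen. Spearman's rho was 0.993 on genes at a TPM of 1 or more. The coefficient of variation was 8.51% with any count above 0 and 7.04% at a CPM of 5. Genes 2-fold higher in replicate 1 numbered 290 on TPM, and 2051, 67 and 28 at mean counts of 1, 50 and 100; in replicate 2, 206 on TPM, and 1436, 14 and 4. Lower minimums admit genes with more sampling noise. TPM ratios had a median of -0.10 over protein-coding genes, against -0.02 for scaled counts. Heart muscle had a median log2 ratio of 1.11 on TPM and 1.14 after the adjustment. Lists below the 50th percentile numbered 13 against a background of genes at a TPM of 0.1 or more. The embryonic share was 72.7% of beta-like and 26.1% of alpha-like globin without Hbb-bt and Hba-a2, the more abundant copies by the uncertain split, and 14.7% of alpha-like globin on estimated counts. Where an alternative changed no set of genes, the cause was not tested. The main transcript was shared by 94.2% of genes at a TPM of 10 and 99.0% where it held 60% or more. Over all alternatives, 17 to 19 pairs were ordered, 7 to 9 lists lay outside the central 95% between libraries and 9799 to 18359 genes were detected.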

Other observations

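Long intergenic non-coding and antisense genes had higher ratios of replicate 1 to replicate 2 than protein-coding genes of like level, classes compared after their values were seen. Among genes with a mean of 50 or more counts, 143 long intergenic non-coding RNAs had a median log2 ratio of replicate 1 to replicate 2 of 0.18 and 129 antisense genes one of 0.17, against -0.02 for 12468 protein-coding genes. After the adjustment for GC content, length and expression, which was chosen after the data were seen, these medians were 0.12, 0.11 and -0.02. The central 95% of medians of 10000 random sets of protein-coding genes, matched on level and number, was -0.03 to 0.06 for the first class and -0.04 to 0.07 for antisense genes, or -0.06 to 0.03 and -0.07 to 0.04 after the adjustment. The 206 processed pseudogenes at that minimum had a median of 0.03 before the adjustment and -0.07 after it, outside their ranges (-0.03 to 0.02 and -0.04 to 0.00) on opposite sides, so no direction is given for them. Rn7sk, a regulator of transcription elongation (0.43, interval 0.26 to 0.60), and Rpph1, the RNA part of ribonuclease P (0.79, interval 0.56 to 1.03), were also higher in replicate 1, whereas Gas5 differed less (0.09). Strand use in counting is not given in the sources used here, so reads of an antisense gene and of its partner were not separated with certainty.

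The 5 non-coding genes of the imprinted list, H19, Meg3, Rian, Mirg and Kcnq1ot1, a group chosen after its values were seen, were higher in replicate 1, with log2 ratios from 0.33 to 0.40. H19 had a log2 ratio of 0.39 (interval 0.35 to 0.42) and Meg3 one of 0.33 (0.30 to 0.36), while Dlk1, the protein-coding neighbour of Meg3 on chromosome 12, had one of -0.04 (-0.07 to -0.01) and Igf2, the neighbour of H19 on chromosome 7, one of 0.26 (0.23 to 0.30).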
